A study of Mus musculus with 8 samples.

How the data were processed

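The series holds RNA sequencing of renal cortex from 8 mice at postnatal day 7, 4 Cre-negative controls and 4 Six2-Tfam knockout mutants, and each library was assigned to its group by its title and mouse line. Per the labels, RNA was isolated with a Qiagen RNeasy kit with a DNase step, and libraries were made and sequenced by a company. Per the submitters' processing notes the reads were processed with Bowtie2, TopHat2, HTSeq and DESeq2 on build mm10, and versions, strandedness and the annotation release are not given in the sources used here. The deposited table holds, per the file headers, a read count and an FPKM value per gene and mouse. The FPKM values are the authors' counts scaled by gene length and by the total of counted reads, with 1 length per gene that recomputes identically in every mouse, and were not used in tests. The authors also give a mean signal per group, which equals the mean of counts divided by DESeq2 size factors. The authors' log2 fold change is deposited as mutant over control and is shrunken towards 0 for low counts, and the authors' p-value and adjusted p-value come with it.

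The table lists 35275 genes, of which 23229 had counts and 12046 were 0 in every mouse. Positions were taken from GENCODE M21 on the same build through Ensembl identifiers, which matched 34490 genes and left 785 without a position. Total counts per mouse ranged from 15597762 to 20417550, which sets the precision of low counts, and folds against a group with 0 counts used a floor of 3 counts over the group. Exact 95% intervals of count ratios came from SciPy, and intervals and floors cover counting error alone.

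Counts were tested with edgeR 4.0.16 in R 4.3.3, with the filterByExpr filter, TMM normalization, quasi-likelihood tests, and Benjamini-Hochberg adjustment at 0.05. The filter left 15028 genes. The share of mitochondrial mRNAs was compared with a two-sided exact permutation test over 70 assignments. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 34 lists, and with fry, which tests whether the genes of a list move one way without comparing them with other genes. Of 38 lists with 723 genes, 716 genes matched the table by symbol or synonym. Not matched were mt-Rnr1, mt-Rnr2, Atp5i, Atp5md, Hbb-b1, Hbb-b2 and Ahsp. Lists with fewer than 3 tested members (mitochondrial rRNA, adrenal and adipose) were not tested as sets, and the sex-linked genes served as a check of the libraries. Acsm2, C1qa, Cdkn1a, Cyp4b1, Slc2a1, Slc4a1 and Slc7a11 each stand on more than 1 list.

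The groups, tests, gene lists, naming rule and the other settings listed first below were chosen before the data were examined. Named genes were Tfam, the 13 mitochondrial mRNAs, and the 10 largest rises and 10 largest falls among genes with a symbol, an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the groups. In each list up to 4 members with the smallest adjusted p were added, and any other gene named was chosen after its values were seen. Not all genes that this rule takes are given by name, and one is not reported here. These settings were DESeq2 1.42.0, limma-voom, median-ratio size factors, library sizes without mitochondrial genes, no filter, a filter at 10 CPM, a threshold of 1 log2 unit, each mouse left out in turn, and a term for the range of mouse numbers. For lists they were an estimated correlation, fry and mitochondrial genes left out, and for the mitochondrial share the protein-coding counts as denominator. A sex term, Mut1819 alone against the 4 controls, and the genes of chromosomes X and Y left out were added after the sex-linked counts were seen.

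The pipeline was tested on simulated data with 14761 genes, with 4 false calls of 150. It found 30, 74, 90 and 98% of 50 genes each changed by 1.25, 1.5, 2 and 4-fold. The simulated genes varied independently, few were changed and sex did not differ, so these rates need not hold for the real libraries. Pairs of libraries within groups were checked for duplicates, and the reduced chi-square of the 12 pairs ranged from 4.63 to 42.3, above the level of counting noise. The coverage of mitochondrial mRNAs by nuclear transcripts at 99% identity or more was found with BLAST 2.17.0. The authors' adjusted p-value in the deposited table was under 0.05 for 7028 genes, of which 6689 were among the 6948 genes changed here, all with the same sign. Another 339 were called by the authors alone and 259 here alone. Tables were handled with Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9.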

Results

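Gene expression was measured by RNA sequencing of renal cortex from mice at postnatal day 7. The 8 libraries came from 4 Cre-negative control mice and 4 mutant mice of a Six2-Tfam knockout line, 1 library per mouse. Six2 marks the progenitors of the nephron, so a Cre recombinase driven by Six2 acts in nephron epithelium, whereas the collecting duct, vessels, stroma and immune cells arise from other progenitors. Tfam encodes the protein that packages mitochondrial DNA and starts its transcription. Counted reads per library numbered 16098284, 17976888, 15597762 and 16999339 in controls Con1391, Con1452, Con1822 and Con1823, and 19959013, 16968196, 20417550 and 17354014 in mutants Mut1393, Mut1453, Mut1454 and Mut1819. The comparison of mutants with controls asks how the transcriptome of the renal cortex differs when nephron epithelium lacks Tfam. No library had Cre with intact Tfam, so the comparison cannot tell effects of Tfam loss from those of the Cre transgene. Values per gene are CPM, counts scaled to a common library size, as mean ± SD over 4 mice, and log2 fold changes are mutant over control, as are sizes given after rose by or fell by. Genes given by name with a rise or a fall had all 4 mutants beyond all 4 controls, except Sesn1, Vim and Vldlr, whose groups overlapped.

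Tfam mRNA, the mitochondrial share of counts and the 12 mitochondrial mRNAs tested were lower in every mutant than in every control. Tfam (ENSMUSG00000003923, mm10 chromosome 10, 71225464 to 71238280, minus strand) went from 53.1 ± 2.96 to 27.0 ± 0.465 CPM, a log2 fold change of -0.98 (SE 0.06, adjusted p = 1.58e-07). The 13 mitochondrial mRNAs together made up 5.95% ± 2.37 of the counts in controls and 1.36% ± 0.325 in mutants, a difference of -4.59 percentage points and a ratio of 4.38. The shares were 4.75, 9.28, 3.88 and 5.88% in controls Con1391, Con1452, Con1822 and Con1823, and 1.84, 1.15, 1.18 and 1.26% in mutants Mut1393, Mut1453, Mut1454 and Mut1819. A two-sided exact permutation test gave p = 0.0286, the smallest that 4 mice against 4 can give. All 12 mitochondrial mRNAs with enough counts to test fell, with a median log2 fold change of -2.24 and a range from -2.54 for mt-Co3 to -1.94 for mt-Co2. The one with the most counts, mt-Co1 (chromosome M, 5328 to 6872), which encodes a core subunit of cytochrome c oxidase, went from 22688 ± 10125 to 4811 ± 1301 CPM. mt-Cytb fell by 2.28 and mt-Nd6, the mRNA read from the opposite strand, fell by 2.03 on the log2 scale. Strandedness is not given, so the mt-Nd6 counts could include reads from the other strand. mt-Nd4l, with 36 counts over the controls and 10 over the mutants, did not reach the filter, and its groups overlapped, with 6 counts in Mut1393 and 2 in Con1822. As a set the mitochondrial mRNAs had an adjusted p = 1.42e-07, and adjusted p = 0.332 with an estimated correlation between genes. Nuclear copies of near-identical sequence cover over 99% of mt-Co2, mt-Co3, mt-Atp6 and mt-Nd3, whose counts are therefore uncertain. They cover none of mt-Nd1, mt-Nd2, mt-Nd5, mt-Nd6 or mt-Cytb. In controls mt-Co2, mt-Co3, mt-Atp6 and mt-Nd3 averaged 9.24 to 43.2 CPM, against 22688 for mt-Co1. The share therefore rests almost wholly on the other mRNAs, and both ends of the range above come from uncertain counts. Within the 1300, 1400 and 1800 ranges of the mouse numbers, whose meaning the labels do not give, the log2 ratio for Tfam was -1.01, -1.03 and -0.91, and the mitochondrial share differed by -2.91, -8.12 and -3.62 percentage points.

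**Figure D1:**
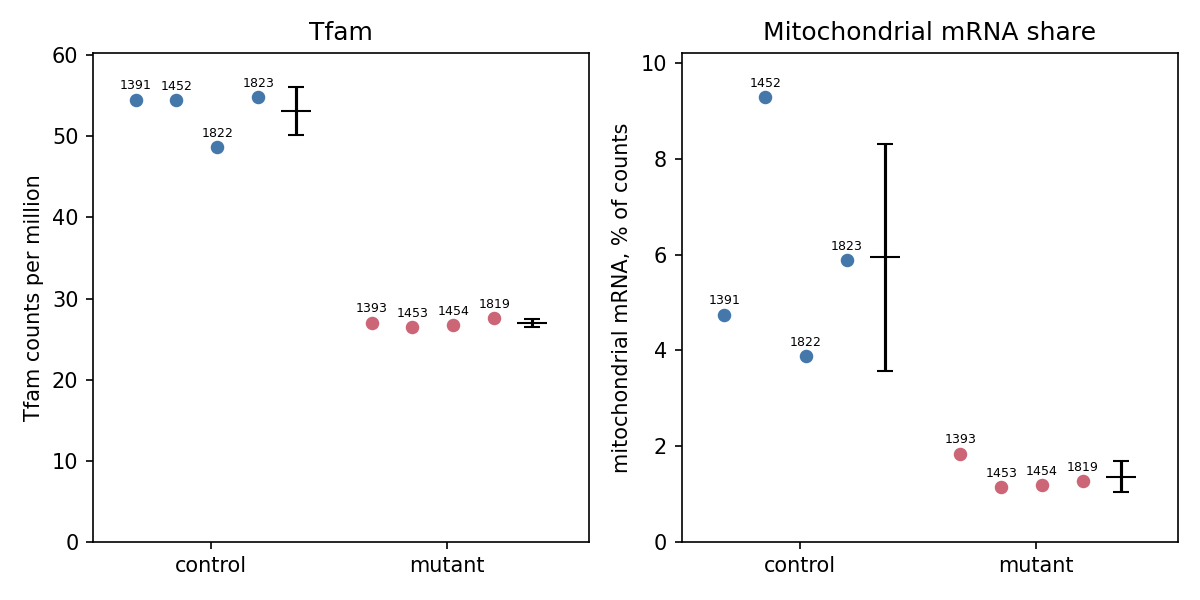
Tfam mRNA in CPM and the share of counts from mitochondrial mRNAs in percent, with 1 point per mouse and the mean ± SD of 4 mice. The 4 mutants lie below the 4 controls in both plots, with mitochondrial shares from 1.15 to 1.84% against 3.88 to 9.28%.

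Of 15028 genes tested with edgeR, 6948 (46.2%) changed at an adjusted p of 0.05, of which 3532 were higher and 3416 lower in mutants. Changes larger than 1 log2 unit numbered 559 upward and 895 downward. The first principal component held 74.7% of the variance and separated the groups. The groups also differed in sex-linked transcripts. Xist, the RNA made from the inactive X chromosome, had 11176, 15593, 10275 and 12641 counts in controls Con1391, Con1452, Con1822 and Con1823, and 141, 52, 13 and 13831 in mutants Mut1393, Mut1453, Mut1454 and Mut1819. The 4 Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y together had 0, 2, 3 and 2 counts in the controls, and 4915, 4294, 4862 and 27 in the mutants. With a term for the libraries with Y-linked counts, which leaves Mut1819 as the single mutant without them, 3967 genes passed, 1891 higher and 2076 lower. In that fit 6945 of the 6948 genes had the same sign. Mut1819 was itself among the mutants used to call these genes. Of the 6948, 6025 (86.7%) had all 4 mutants beyond all 4 controls. The agreement in sign is therefore not an independent check.

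**Figure D2:**
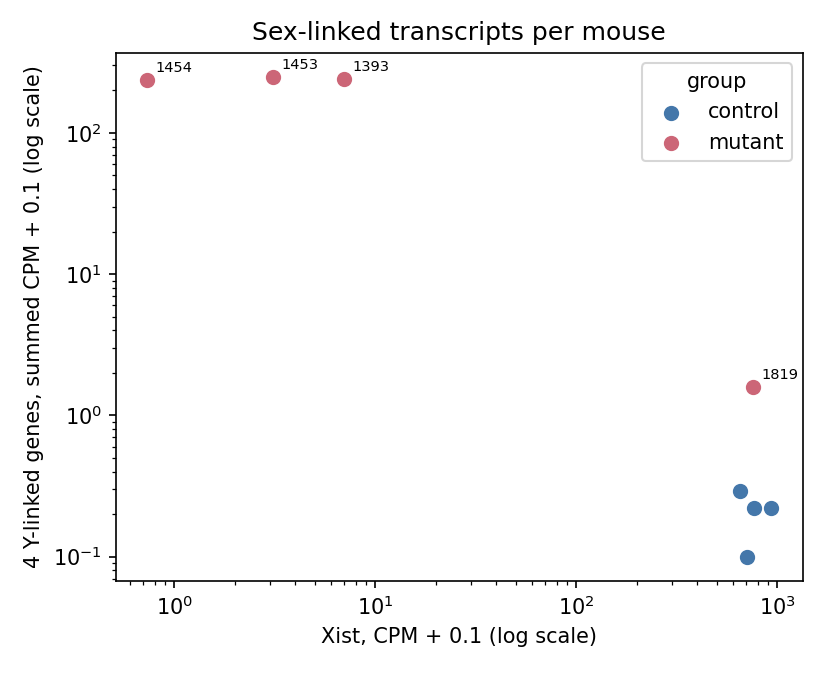
Xist and the sum of 4 Y-linked genes per mouse, in CPM plus 0.1 on log axes, with 1 point per mouse. Mut1819 has 13831 Xist counts and 27 Y-linked counts, while mutants Mut1393, Mut1453 and Mut1454 have 4294 to 4915 Y-linked counts and the controls 0 to 3.

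The largest rises included stress-related and secreted genes, such as Trib3, Chac1, Areg and Ostn. Trib3, a pseudokinase induced in the integrated stress response, went from 1.19 ± 0.299 to 173 ± 24.9 CPM (log2 fold change 7.18, SE 0.16, adjusted p = 9.43e-11). Chac1, a glutathione-degrading enzyme induced by the same response, rose by 6.16. Areg, which encodes the epidermal growth factor receptor ligand amphiregulin, reached 22.4 ± 4.96 CPM from 5 counts over the 4 controls, a log2 fold change of 8.06. Ostn, which encodes the secreted peptide osteocrin, reached 36.1 ± 7.61 CPM, also from 5 control counts, a log2 fold change of 8.74. Cdsn, which encodes the adhesion protein corneodesmosin, rose by 6.93, the secretory granule protein gene Vgf by 6.65 and the peroxidase gene Lpo by 6.54. Pla2g2e, a secreted phospholipase gene on chromosome 4 (138877942 to 138882817), had 0 counts over the controls and 409 over the mutants, at least 115-fold higher against a floor of 3 counts over the 4 controls. Vmn2r3, a vomeronasal receptor gene on chromosome 3 (64257215 to 64289709), had 0 and 383 counts, at least 108-fold higher against the same floor. Ddx3y, on the Y chromosome, had 3 and 6265 counts, a ratio of 1768 with an exact 95% interval from 605 to 8575, and Mut1819 held 12 of the 6265. Such intervals and floors cover counting error alone.

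The largest falls included genes known from the proximal tubule, such as Kap and Miox. Kap, the androgen-regulated kidney protein, went from 1419 ± 180 to 46.2 ± 38.3 CPM (log2 fold change -4.94, SE 0.44, adjusted p = 2.81e-06). Miox, the enzyme that opens the ring of myo-inositol, went from 511 ± 113 to 26.4 ± 11.8 CPM, a log2 fold change of -4.27. Apom, an apolipoprotein that carries sphingosine 1-phosphate, went from 75.1 ± 11.3 to 3.01 ± 1.81 CPM, a log2 fold change of -4.62. Mep1b, a subunit of the brush border protease meprin, changed by -4.53. The other large falls were in Defb19 (-4.78), a defensin gene, Slc10a1 (-4.45), a bile acid transporter gene, F13b (-4.35) and Proz (-4.25), which encode coagulation proteins, Nepn (-4.35) and the retinol dehydrogenase gene Rdh19 (-4.22).

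Gene lists fixed beforehand were tested with limma's camera at a preset correlation between genes, and 10 of 34 were higher and 11 lower in mutants. With the correlation estimated per list, camera called 0 lists, with 6 at an unadjusted p under 0.05, and fry called 10 higher and 12 lower. At the preset correlation, splits of the libraries with 2 controls and 2 mutants on each side called up to 14 lists. Adjusted p-values of lists at that correlation can therefore be too small. The number of members that changed, adjusted over the list alone, was equal to that over all genes for 23 lists and is given for each of the other 11. Genes of a list named beyond the 4 with its smallest adjusted p were chosen after their values were seen.

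**Figure D3:**
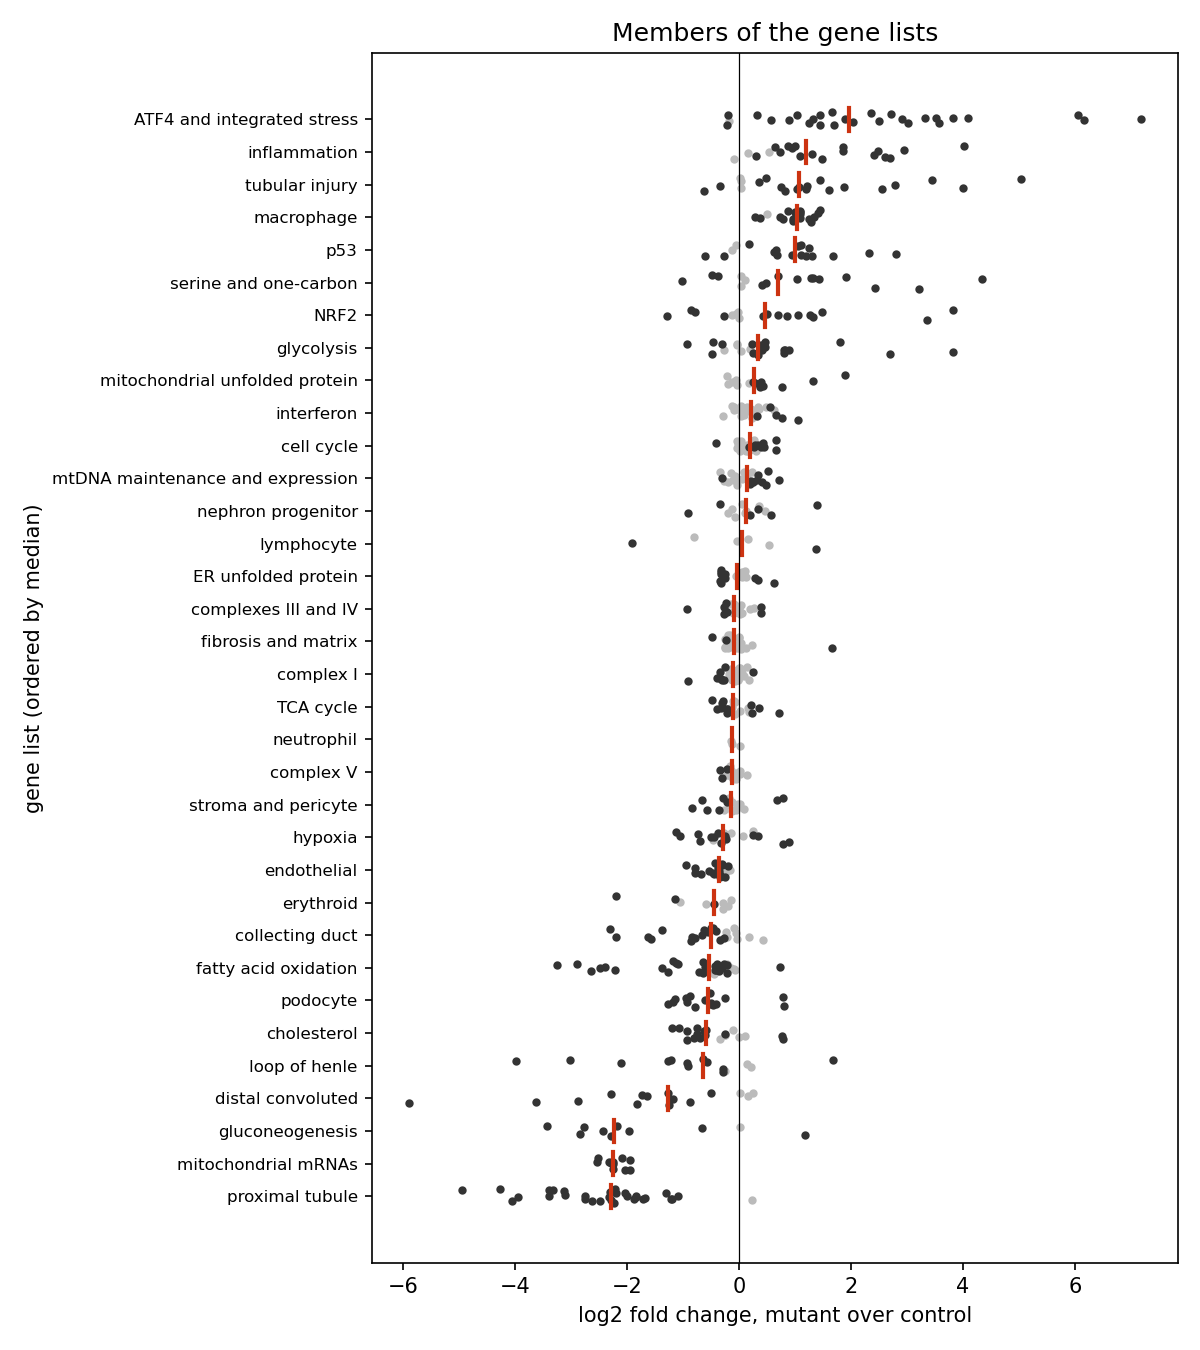
Log2 fold change, mutant over control, of the members of each of the 34 gene lists, with 1 point per gene, dark where the gene passed and grey where it did not, and a red mark at the median. The proximal tubule list lies lowest with a median of -2.27 and the list of the integrated stress response highest with a median of 1.97.

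Genes of the integrated stress response, which is carried by the transcription factor ATF4, rose together. Of 28 measured members, 25 rose, 2 fell and 1 did not pass, with a median log2 fold change of 1.97 (adjusted p = 1.03e-17, and adjusted p = 0.138 with an estimated correlation). Atf5, a transcription factor of this response, went from 20.5 ± 1.28 to 244 ± 18.9 CPM, and Ddit3, which encodes CHOP, from 7.82 ± 0.757 to 90.1 ± 9.54 CPM. Slc7a3, a cationic amino acid transporter, rose by 6.05 and Asns, which makes asparagine, by 4.09. Gdf15, a circulating signal of cell stress, rose by 3.03, and Fgf21, another such signal, had 1 count over the controls and 43 over the mutants, a ratio of 36.4 with an exact 95% interval from 6.19 to 1471. The members that fell were Slc3a2 (-0.21) and Vldlr (-0.18), and Cth had a log2 fold change of -0.18. In the list of serine, proline and one-carbon metabolism, 11 of 17 members rose and 3 fell, with a median of 0.69 (adjusted p = 0.000463, and adjusted p = 0.388 with an estimated correlation). The rises were led by the mitochondrial folate enzymes Aldh1l2 (4.33) and Mthfd2 (3.21), followed by the serine enzyme Psat1 (2.42), the proline enzyme Aldh18a1 (1.91) and Pck2 (1.28). The members that fell, Aldh1l1 (-1.01), Mthfd1 (-0.49) and Shmt1 (-0.36), encode cytosolic enzymes of the folate cycle.

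Chaperones and proteases of mitochondria rose in part, and those of the endoplasmic reticulum did not move as a group. In the list of the mitochondrial unfolded protein response, 8 of 14 members rose and 6 did not pass over all genes, with 9 rising and 1 falling when adjusted over the list alone. Its median was 0.27 (adjusted p = 0.0147, and adjusted p = 0.582 with an estimated correlation), and the sex term, with which 3 members rose and 1 fell, ended the call (adjusted p = 0.0798), as did Mut1819 alone (0.0582), in a range from 0.00143 to 0.582 over the settings tried. Lonp1, the matrix protease that degrades TFAM, went from 140 ± 4.95 to 520 ± 49.0 CPM (log2 fold change 1.89), and the matrix chaperone Hspa9 rose by 1.32 and its partner Dnaja3 by 0.76. Of 16 genes of the unfolded protein response of the endoplasmic reticulum, 3 rose, 7 fell and 6 did not pass, or 1 rose and 1 fell with the sex term, with a median of -0.03 (adjusted p = 0.526). Dnajb9 rose by 0.62, while the co-chaperone gene Dnajc3 had a log2 fold change of -0.25.

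Genes for glycolysis rose and those for glucose production and fatty acid oxidation fell, the latter 2 together with the proximal tubule markers, whose median was -2.27 and which share Acsm2 and Cyp4b1 with the fatty acid list. Of 23 glycolysis genes, 14 rose and 4 fell, or 15 and 4 adjusted over the list alone and 9 and 3 with the sex term, with a median of 0.35 (adjusted p = 0.00263, and adjusted p = 0.516 with an estimated correlation). Hexokinase Hk2 went from 2.74 ± 0.770 to 39.0 ± 7.25 CPM (log2 fold change 3.83), and Eno2 rose by 2.70, Pfkp by 1.80 and Aldoa by 0.80. Of 10 gluconeogenesis genes, 8 fell, Got1 rose by 1.18 and Gpt did not pass, with a median of -2.23 (adjusted p = 7.63e-05, and adjusted p = 0.291 with an estimated correlation). Pyruvate carboxylase, Pcx, went from 806 ± 180 to 74.9 ± 29.1 CPM (log2 fold change -3.43), and the glucose transporter Slc2a2 fell by 2.77 and the glucose 6-phosphate transporter Slc37a4 by 2.28. Of 30 genes for fatty acid oxidation, 24 fell and 1 rose, or 25 and 1 adjusted over the list alone, with a median of -0.52 (adjusted p = 7.07e-09, and adjusted p = 0.388 with an estimated correlation). Acsm1 fell by 3.25, Acaa1b by 2.39, Hadh by 1.26 and the medium-chain dehydrogenase Acadm by 1.12, while Pdk4, a kinase that restrains pyruvate oxidation, rose by 0.74. Of 20 genes for cholesterol synthesis and uptake, 12 fell and 2 rose, or 13 and 2 adjusted over the list alone, with a median of -0.59 (adjusted p = 0.000463, and adjusted p = 0.560 with an estimated correlation). Hmgcs1 fell by 1.20, Stard4 by 1.06 and Mvd by 0.93, and Sqle and Fdps rose by 0.79 and 0.77. Of 21 genes of the citric acid cycle, 4 rose and 8 fell, with a median of -0.10 (adjusted p = 0.305). The list was called lower with the range term (0.0460, with 4 rising and 11 falling) and the sex term (0.00854, with 1 and 7), in a range from 0.00854 to 0.872. Citrate synthase, Cs, rose by 0.72, while Suclg1 fell by 0.47 and the complex II subunit Sdhd by 0.39.

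Nuclear genes for the respiratory chain moved far less than the mitochondrial mRNAs. Of 36 complex I genes, 7 fell and 1 rose, or 4 and 1 adjusted over the list alone, with a median of -0.10 (adjusted p = 0.0973). This depended on the settings, and the list was called lower with the range term (0.00502, with 15 falling and 1 rising), the sex term (0.00233, with 4 falling), Mut1819 alone (0.00131), and without Con1822 (0.0117) or Mut1454 (0.00777), in a range from 0.00131 to 0.835. Ndufb2 fell by 0.92 and Ndufv3 by 0.39. Of 21 genes for complexes III and IV with cytochrome c, 2 rose and 5 fell, with a median of -0.08 (adjusted p = 0.479, in a range from 0.0450 with Mut1819 alone to 0.984). The sex term left 0 of the 21 past the threshold in edgeR, with 6 at an unadjusted p under 0.05. Cycs, which encodes cytochrome c, rose by 0.39, but with the sex term it was 0.25 and missed the threshold. Of 16 complex V genes, 3 fell, or 1 adjusted over the list alone, with a median of -0.13 (adjusted p = 0.0973). This list too was called lower with the range term (0.00508, with 11 falling), Mut1819 alone (0.00758), and without Con1822 (0.0316) or Mut1454 (0.0155), in a range from 0.00508 to 0.790. The sex term also called it (0.0122), though it left 0 of the 16 genes past the threshold in edgeR, with 4 at an unadjusted p under 0.05. Atp5e fell by 0.30, but with the sex term it was -0.24 and missed the threshold. In the list for maintenance and expression of mitochondrial DNA, 9 of 27 genes rose and 1 fell, or 9 and none adjusted over the list alone, with a median of 0.14 (adjusted p = 0.0946). It was called higher by fry (0.00212), without a filter (0.0276) and without Con1452 (0.0473), in a range from 0.00212 to 0.425. Lrpprc, which stabilises mitochondrial mRNAs, rose by 0.72, the helicase gene Supv3l1 by 0.52, the tRNA-processing gene Elac2 by 0.48 and the helicase gene Peo1 by 0.42. Polrmt, the mitochondrial RNA polymerase, had a log2 fold change of -0.11 (adjusted p = 0.222).

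The marker lists of the nephron segments were lower, most of all those of the proximal tubule. Of 31 proximal tubule markers, 30 fell and 1 did not pass, with a median of -2.27 (adjusted p = 2.69e-18, and adjusted p = 0.238 with an estimated correlation). The organic anion transporter Slc22a8 went from 211 ± 41.2 to 24.3 ± 6.47 CPM (log2 fold change -3.11), and Slc13a3 fell by 2.75, the urate transporter Slc22a12 by 2.22 and Slc7a8 by 1.88. The phosphate transporter Slc34a1 fell by 3.39, the endocytic receptor Lrp2 by 2.32 and the transcription factor Hnf4a by 1.30, and Slc17a1 had a log2 fold change of 0.23 (adjusted p = 0.166). Of 15 distal convoluted tubule markers, 12 fell, with a median of -1.27 (adjusted p = 2.24e-07, and adjusted p = 0.145 with an estimated correlation). Kallikrein, Klk1, went from 369 ± 34.5 to 30.1 ± 6.13 CPM, the thiazide-sensitive cotransporter Slc12a3 fell by 2.28, Klhl3 by 1.64 and Wnk1 by 1.25. Of 15 markers of the loop of Henle, 11 fell and 1 rose, or 12 and 2 adjusted over the list alone, with a median of -0.65 (adjusted p = 0.000463, and adjusted p = 0.400 with an estimated correlation). Egf went from 56.9 ± 9.62 to 3.54 ± 1.30 CPM and Ppp1r1a fell by 2.10, while the prostaglandin receptor Ptger3 rose by 1.68. Of 16 podocyte markers, 14 fell and 2 rose, with a median of -0.56 (adjusted p = 1.72e-05, and adjusted p = 0.238 with an estimated correlation). Nphs1, which encodes nephrin of the slit diaphragm, fell by 1.13, Mapt by 1.18 and Npnt by 0.92, and Cd2ap and Ptgds rose by 0.78 and 0.80.

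Among cell type lists other than those of the nephron segments, collecting duct and endothelial markers were lower and macrophage markers higher. Of 23 collecting duct markers, 16 fell, with a median of -0.50 (adjusted p = 3.59e-06, and adjusted p = 0.238 with an estimated correlation). The falls with the smallest adjusted p were in genes of intercalated cells, namely pendrin Slc26a4 (-2.30), Slc4a9 (-1.58), Insrr (-1.62) and Slc4a1 (-2.19), while the principal cell water channel Aqp2 had a log2 fold change of 0.42 (adjusted p = 0.233). Of 19 endothelial markers, 16 fell, or 18 adjusted over the list alone and 7 with the sex term, with a median of -0.35 (adjusted p = 1.46e-06, and adjusted p = 0.291 with an estimated correlation). Ehd3, a marker of glomerular endothelium, fell by 0.95, the angiopoietin receptor Tek by 0.78 and the transcription factor Erg by 0.67. Of 20 macrophage markers, 19 rose and Lst1 did not pass, with a median of 1.03 (adjusted p = 8.05e-08, and adjusted p = 0.257 with an estimated correlation). The mannose receptor Mrc1 went from 21.7 ± 1.53 to 55.3 ± 6.25 CPM, and the complement genes C1qc, C1qb and C1qa rose by 1.26, 1.09 and 1.09. Of 18 markers of stroma and pericytes, 2 rose and 6 fell, or 2 and 2 with the sex term, with a median of -0.14 (adjusted p = 0.169, in a range from 0.0480 without Con1452 to 0.759), and the renin gene Ren1 went from 365 ± 60.5 to 205 ± 59.1 CPM. Of 14 nephron progenitor genes, 4 rose and 2 fell, or 1 and 1 with the sex term, with a median of 0.12 (adjusted p = 0.405), and Eya1 went from 1.54 ± 0.275 to 4.06 ± 0.626 CPM.

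Genes of tubular injury, inflammation and p53 signalling rose. Of 21 injury markers, 16 rose and 2 fell, with a median of 1.07 (adjusted p = 2.24e-07, and adjusted p = 0.138 with an estimated correlation). Lcn2, which encodes the injury marker NGAL, went from 6.03 ± 3.18 to 196 ± 27.2 CPM (log2 fold change 5.03), Tnfrsf12a rose by 1.87 and Vcam1 by 1.45. Krt20 rose by 3.99, Havcr1, which encodes KIM-1, by 3.45 and Sox9 by 2.56, and Igfbp7 and Vim fell by 0.62 and 0.33. Of 20 inflammation genes, 17 rose and 3 did not pass, with a median of 1.20 (adjusted p = 8.05e-08, and adjusted p = 0.138 with an estimated correlation). They moved with the macrophage markers, whose median was 1.03 and whose list also holds C1qa. Il34, a ligand of the macrophage receptor CSF1R, went from 9.46 ± 1.89 to 61.1 ± 6.93 CPM, Nfkbiz rose by 1.48, and the chemokine genes Cxcl16 and Cx3cl1 by 0.99 and 0.88. Of 18 genes induced by p53, 14 rose and 2 fell, with a median of 1.0 (adjusted p = 3.21e-06, and adjusted p = 0.138 with an estimated correlation). The cell cycle inhibitor Cdkn1a, which is also on the injury list, went from 68.4 ± 5.59 to 158 ± 12.9 CPM, Aen rose by 1.30, Zmat3 by 1.25 and Btg2 by 1.12, while Fas and Sesn1 fell by 0.60 and 0.27. Of 18 genes of the NRF2 oxidative stress response, 10 rose and 4 fell, with a median of 0.47 (adjusted p = 0.0310, and adjusted p = 0.698 with an estimated correlation). The cystine transporter Slc7a11, also on the integrated stress response list, rose by 3.83, Txnrd1 by 1.33, Srxn1 by 1.27 and G6pdx by 0.87. The NRF2 call ended with the sex term (adjusted p = 0.153), with Mut1819 alone (0.0774), with a term for mouse number range (0.0719), without Con1822 (0.0513) and without Mut1454 (0.0529), in a range from 0.00397 to 0.698 over the settings tried.

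Other lists gave smaller or mixed changes. Of 30 cell cycle genes, 9 rose and 1 fell, or 5 and 1 adjusted over the list alone, with 16 rising with the sex term and 12 with the range term, and a median of 0.19 (adjusted p = 0.0150, and adjusted p = 0.708 with an estimated correlation). Ccne1, which drives entry into S phase, rose by 0.67 and the mitotic cyclin Ccnb1 by 0.43, and the list missed the threshold without Con1823 (adjusted p = 0.0541), without Mut1819 (0.0884) and with fry (0.183). Its adjusted p ranged from 9.70e-07 to 0.708 over the settings tried. Of 26 interferon-induced genes, 5 rose, or 4 adjusted over the list alone, with a median of 0.22 (adjusted p = 0.0501). That list was called higher with the range term (0.0110, with 10 rising), the sex term (0.00418, with 2 rising), Mut1819 alone (0.00381), without a filter (0.00920) and without Con1391 (0.0466), Con1823 (0.0134), Mut1453 (0.0162) or Mut1454 (0.0215), in a range from 0.00381 to 0.681. Tmem173, which encodes STING, rose by 0.56 and Oas1a by 1.05. Of 20 hypoxia genes, 4 rose and 10 fell, or 2 and 4 with the sex term, with a median of -0.27 (adjusted p = 0.0946). Fry (2.04e-05) and the test without a filter (0.0427) called the list lower, in a range from 2.04e-05 to 0.291. Among these, Ero1l rose by 0.79, and Car12, Bnip3 and Pdk1 fell by 1.12, 0.73 and 0.49. Of 23 genes of fibrosis and extracellular matrix, 1 rose and 2 fell, with a median of -0.08 (adjusted p = 0.346). Timp1, an inhibitor of matrix proteases, rose by 1.65, and Thbs1 fell by 0.47, but with the sex term it was -0.39 and missed the threshold. Of 9 erythroid genes, 3 fell, or 5 with the range term, with a median of -0.45 (adjusted p = 0.0261, and adjusted p = 0.418 with an estimated correlation), and the list missed the threshold without Con1391 (0.0567), in a range from 0.00758 to 0.418. One of these 3 was Slc4a1, which the collecting duct list also holds. Of 6 lymphocyte genes, Lck rose by 1.38 and Cd8a fell by 1.91, with a mean of -0.11, a median of 0.07 and an upward test (adjusted p = 0.902). The neutrophil genes S100a8, S100a9 and Csf3r had log2 fold changes of -0.12, -0.13 and 0.02, none past the test (list adjusted p = 0.944). Of the adrenal and adipose markers 1 each was measured, too few to test as lists. Star, of steroid synthesis, had a log2 fold change of -0.56 (adjusted p = 0.0210, and adjusted p = 0.109 with the sex term and 0.121 with Mut1819 alone), and it missed the threshold without Con1452 (0.0509) or Con1823 (0.0623) and without Mut1453 (0.0537), Mut1454 (0.0580) or Mut1819 (0.0563), in a range from 0.0110 to 0.121. Fabp4, the fatty acid binding protein of adipocytes, had a log2 fold change of -0.25 (adjusted p = 0.243).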

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

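All tests of explanations here, and the sex term, were chosen only after the results were seen. In 25 of 332 groups of 4 mice 1 mouse stood far from the other 3, where chance flags about 1 in 20 groups, or 16.6, and 13 of the 25 were in Mut1393.

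The first pattern is the difference in sex-linked transcripts between the groups, where Mut1819 stood apart from the other mutants. It had 758.5 CPM of Xist against 0.633 to 6.87 in the others, and 0.6581 CPM of Ddx3y against 101.7 to 111.6, and its Y-linked counts were 0.613% of the other mutants' mean, so the group difference in these genes is consistent with 4 female controls, 3 male mutants and 1 female mutant. A difference in sex as the whole cause of the autosomal changes is argued against by the fit with a sex term, in which 55.05% of the 6719 autosomal genes passed again with the same sign, although that term rests on 1 mutant library without Y-linked counts. For the 3020 genes that no longer passed, sex and genotype cannot be told apart: their median log2 fold change went from 0.322 to 0.28, a ratio of 0.869, while their median SE went from 0.084 to 0.134. The sex term itself sets the 3 other mutants against Mut1819 alone. It rests on 1 library there, so it cannot show whether sex changed autosomal genes.

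The second pattern is the fall of proximal tubule markers, for which a lower share of proximal tubule cells is the first technical explanation. Such a loss alone would raise the markers of other cell types alike, but the median of the macrophage list exceeded that of the endothelial list by 1.377 log2 units, and the interquartile ranges of both lists, 0.85 to 1.14 and -0.50 to -0.27, did not overlap. The 31 markers did not share 1 fold change: they spread from -4.94 to 0.23, with an SD 5.17 times their median standard error. This cannot decide on a single dilution factor for all proximal tubule transcripts, because markers also expressed in other cells would spread under such a factor too. A lower share of these cells as part of the cause, a gain of macrophages, and delayed maturation of the tubule stay open and were not tested further.

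The third pattern is Six3, a gene next to Six2 on chromosome 17 (85613608 to 85629302), with 0 counts over the controls and 83 over the mutants, 12 to 28 in each mutant. A candidate explanation is expression from extra gene copies carried by the Six2-Cre transgene, and the nearest tested neighbours on either side, Camkmt and Srbd1, changed by at most 0.164 log2 units. Six2 lies nearer and, too low for the filter, went from 5 to 42 counts, a ratio of 7.11 with an exact 95% interval from 2.82 to 23.0. A change in a neighbour was to count against such copies, but a transgene named for Six2 could carry Six2 as well, so the neighbours decide neither way. Induction by the loss of Tfam cannot be told apart from extra copies, because 0 libraries had Cre with intact Tfam or Tfam loss without Cre.

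The count of 6948 genes was reached by 1 of the 35 splits of the 8 libraries into 4 and 4, the real one. The highest of the other splits had 0 in edgeR, with at most 2260 at an unadjusted p under 0.05. Those splits mix mutants and controls on a side, which widens the spread within sides, so their 0 does not exclude chance. The 21 lists called at the preset correlation were reached by 10 of the 35 splits, and the highest of the other splits called 25, so this count alone does not exclude chance. The 9 others each keep 3 of the 4 mice of a group on 1 side. The 18 splits with 2 controls and 2 mutants on each side hold no difference in genotype, yet called 2 to 14 lists. Adjusted p-values of lists at the preset correlation can therefore be too small. With fry the real split called 22 lists and the highest other split 0. The wider spread within mixed sides bears on fry too, so this 0 does not exclude chance either.

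Mut1393 lay nearer to the controls than the other mutants for several genes that fell. It had 103.5 CPM of Kap against 24.3 to 29.8 in the other mutants, 5.702 of Apom against 1.91 to 2.39, 12.82 of Mep1b against 4.34 to 5.27, and 5.946 of F13b against 2.31 to 2.49. Its mt-Nd5 was 2268 CPM against 1531 to 1629, its mt-Co1 6762 against 4104 to 4210, and its mitochondrial mRNA share 1.84% against 1.15 to 1.26%. Among genes that rose it had 23.2 CPM of Chac1 against 28.2 to 28.5, 39.92 of Elac2 against 45.0 to 45.3, 104.9 of Pck2 against 120 to 123, 113.7 of Aldh18a1 against 132 to 136, and 8.383 of Ccne1 against 12.7 to 13.5. Its Star level was 2.681 CPM against 1.97 to 2.08.

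Mut1453 had 647.9 CPM of Pdia3 against 690 to 694 in the other mutants. Con1452 had 193.3 CPM of Mep1b against 145 to 149 in the other controls, 109.5 of F13b against 51.1 to 56.3, 142.3 of Rdh19 against 67.2 to 78.6, 24.9 of mt-Co3 against 9.78 to 11.5, and 181.6 of Slc37a4 against 126 to 135. Con1823 had 8.942 CPM of Ddit3 against 7.32 to 7.56, and 68.21 of Slc26a4 against 55.1 to 56.7. Con1822 had 48.66 CPM of Tfam against 54.4 to 54.8, and Con1391 had 0 CPM of Ddx3y against 0.0600 to 0.0635. For Ddx3y this is 0 counts against 1 count in each of the other controls.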

How the results depend on the processing

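The sex term, Mut1819 alone and the fit without X and Y genes were chosen after the data were seen, and the other settings below were fixed beforehand. Tfam fell in every alternative, by 0.94 to 0.99 on the log2 scale, and by 0.96 to 1.02 with any mouse left out.

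The count of 6948 genes changed stayed between 5664 and 7245 under the other tools, scalings and filters, the range term and without the X and Y genes. A threshold of 1 log2 unit left 1.5e+03 genes, 559 higher and 895 lower, by its construction. The sex term left 3967, 1891 higher and 2076 lower, and Mut1819 alone left 3761, 1744 higher and 2017 lower, where fewer libraries inform the contrast and the lone mutant is assumed to vary like the others. Leaving out 1 mouse gave 6085 to 7032 genes, 3083 to 3570 higher and 2967 to 3462 lower. The estimated correlation left 0 lists higher and 0 lower, against 9 to 12 and 10 to 15 in the other alternatives, and leaving out 1 mouse gave 9 to 11 higher and 10 to 13 lower. The mitochondrial share differed by -4.65 points with protein-coding counts as denominator, and by -5.28 to -3.48 with 1 mouse left out, where 3 against 4 mice allow no exact permutation p below 0.0571.

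Of 153 named genes that passed, 126 passed in every alternative and 0 changed direction. Of all 6948 genes changed, 3 had the other sign with the sex term and with Mut1819 alone, namely Igsf9, Gm14584 and Fgf12. None of these passed there. Mut1819 was among the mutants used to call the 6948 genes and to name the largest rises and falls. Agreement in sign is therefore not an independent check. The sex term ended the call of 21 named genes and Mut1819 alone that of 22. The sex term left 0 falling members in the integrated stress response, p53, fibrosis and mitochondrial DNA expression lists in edgeR, with 1, 1, 2 and 1 at an unadjusted p under 0.05. Among lists that had not passed, the range term and the sex term each added complex I, complex V, the citric acid cycle and interferon. Mut1819 alone added these and complexes III and IV, fry added mitochondrial DNA expression and hypoxia, and the test without a filter added mitochondrial DNA expression, hypoxia and interferon. Among named genes and lists, values that changed sign had not passed, and the cause was not tested. S100a9 was 0.03 and S100a8 0.15 with the sex term, 0.03 and 0.15 with Mut1819 alone, and -0.373 to 0.165 and -0.310 to 0.407 with 1 mouse left out, where Csf3r was -0.0223 to 0.0831. The adjusted p of the neutrophil list was 0.768 without a filter, 0.977 with the range term, 0.819 with the sex term, 0.819 with Mut1819 alone and 0.636 to 0.928 with 1 mouse left out. With the sex term and with Mut1819 alone the list of the endoplasmic reticulum had 0.934 and 0.900, and that of fibrosis 0.928 and 0.900. The lymphocyte list had 0.646 to 0.973 with 1 mouse left out.

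The labels pair no control with a mutant, so mice were not analysed as pairs, and the number ranges entered as a term instead. In their deviations from the group means, controls and mutants of 1 number range correlated at 0.0546 to 0.259 (mean 0.149), and those of different ranges at a mean of -0.0673. Among the libraries of the other group, each of the 8 correlated best with one of its own range. This is a hint from the data that mice of 1 range share something, and the range term gave 7245 genes. Libraries of the same group were not compared in this way.

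Not run were the alternatives for normalized values, since the table holds counts, and the mitochondrial share with rRNAs and tRNAs, since the table lists the 13 mRNAs alone. Genes with a few counts per library, such as mt-Nd4l, did not reach the filter of the main fit. Fits with other filters tested more genes, 18251 in DESeq2 and 23229 without a filter. Depth alone need not explain the low counts of mt-Nd4l, as a nuclear copy of identical sequence covers 98.99% of it.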

Other observations

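The gene families here were chosen after the table of all genes was seen, and their tests with them. Genes of the cytosolic translation machinery were higher in the mutants, most of all those of ribosomal proteins and tRNA synthetases. Of 77 cytosolic ribosomal protein genes, 76 rose and Rps4l fell by 0.25, with a median log2 fold change of 0.70 (adjusted p = 1.83e-29 over 12 families, and adjusted p = 0.174 with an estimated correlation). Rpl12 rose by 1.26 and the elongation factor gene Eef1a1 rose by 0.61. Of 20 cytosolic aminoacyl-tRNA synthetase genes, 18 rose, with a median of 1.06 (adjusted p = 5.23e-13, and adjusted p = 0.134 with an estimated correlation), among them Sars (1.69), Wars (1.52) and Eprs (1.22). Of 51 translation initiation factor genes, 37 rose and 14 did not pass, against 21 and 30 with the sex term, with a median of 0.29 (adjusted p = 1.81e-10, and adjusted p = 0.134 with an estimated correlation). The mitochondrial counterparts moved less: of 17 mitochondrial synthetase genes 6 rose and 1 fell, or 1 and 1 with the sex term, with a median of 0.05 (adjusted p = 0.267), and of 76 mitochondrial ribosomal protein genes 25 rose and 7 fell, or 8 and 4 with the sex term, with a median of 0.09 (adjusted p = 0.0101, and adjusted p = 0.679 with an estimated correlation). Of 37 proteasome genes, 22 rose and Psmd3 fell by 0.41, with a median of 0.19 (adjusted p = 0.00106, and adjusted p = 0.540 with an estimated correlation), and with the sex term 3 rose and 1 fell.

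Families for transport and detoxification were lower, and no family's median changed sign under the other scalings. Of 21 genes of solute carrier family 22, the organic ion transporters, 18 fell, 4 of the 21 being proximal tubule markers of the list whose median was -2.27, with a median of -2.04 (adjusted p = 1.24e-10, and adjusted p = 0.134 with an estimated correlation). Of 11 UDP-glucuronosyltransferase genes, 8 fell and Ugt1a9 rose by 1.23, with a median of -1.02 (adjusted p = 0.00227, and adjusted p = 0.174 with an estimated correlation). Of 32 cytochrome P450 genes, 16 fell and 3 rose, with a median of -0.33 (adjusted p = 0.00227, and adjusted p = 0.134 with an estimated correlation), and Cyp2j5 fell by 2.93. Of 21 vacuolar ATPase genes, 9 fell and 2 rose, with a median of -0.14 (adjusted p = 0.00866, and adjusted p = 0.540 with an estimated correlation), and Atp6v1b1, a subunit of intercalated cells, fell by 1.28. Among 19 claudin genes, which encode tight junction proteins, 6 rose and 7 fell, with a median of -0.07 and an upward test (adjusted p = 0.943). Cldn4, Cldn3 and Cldn7 rose by 2.09, 1.56 and 1.05, while Cldn2, the pore-forming claudin of the proximal tubule, fell by 1.77. The 3 small proline-rich protein genes measured, known from cornified and injured epithelia, all rose, Sprr2g by 5.19, Sprr2f by 4.52 and Sprr1a by 3.26 (adjusted p = 0.00430, and adjusted p = 0.134 with an estimated correlation).

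Mut1393 lay nearer to the controls than the other mutants. It was the mutant nearest to the controls for 3434 (49.4%) of the 6948 changed genes, against 13.98 to 20.7% for the other mutants. On the first principal component it lay at 32.1, and the other mutants at 45.6 to 48.8. Its Tfam level of 27.0 CPM lay within the 26.5 to 27.6 CPM of the other mutants.

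The nuclear copies of mitochondrial sequence lie on chromosome 1 between 24611535 and 24616197. They cover 99.1% of mt-Nd3, 98.99% of mt-Nd4l, 99.9% of mt-Co3, 99.6% of mt-Co2, 99.6% of mt-Atp6, 63.6% of mt-Nd4, 31.3% of mt-Co1 and 21.1% of mt-Atp8.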
